A study of Choristoneura fumiferana multiple nucleopolyhedrovirus with 11 samples.

How the data were processed

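The 11 arrays carried one time course of Cf203 cells, an insect cell line, infected with Choristoneura fumiferana multiple nucleopolyhedrovirus (CfMNPV), a baculovirus of the spruce budworm. Per the labels, total RNA from each time was copied with an oligo-dT primer into Cy3-labelled cDNA, and CfMNPV genomic DNA labelled with Cy5 by nick translation was hybridised to the same array as an equimolar reference. Per the labels there was 1 array at each of 0, 1, 3, 6, 9, 12, 18, 24, 36, 48 and 72 h after infection (hpi). No time had a second array, so the spread that enters each test is the scatter of single arrays around a fitted line or window mean, and the labels do not say whether the times came from separate cultures. The number of arrays limits the precision.

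The deposited array tables gave, per the file headers, the foreground and local background intensity of 1152 spots in each channel, as spot medians, means and SDs. The scanner and its software are not given in the sources used here. The 1152 spots held 310 oligos. Among them were 146 named cforf and a number, taken here as sense probes of the 146 viral open reading frames (ORFs), and 146 whose names add nc, taken here as their complements, with 3 spots for each probe. The other 18 names were controls, with 12 spots for each control oligo and 72 blank spots. The files do not pair the ORF numbers with gene names, and no gene was named from its number. Because the files do not pair them, few ORF identifiers are named. Those named for a comparison were the first 2 under each rule fixed before the data were examined, which ranked probes by slope, by window change, by onset or by the log2 ratio at 72 hpi. The 9 gene lists fixed before the data were examined matched 0 ORFs by name, so no gene list was tested.

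The authors' deposited value column held the log2 ratio of background-subtracted Cy3 over Cy5 for 10 of the arrays. For the 1 hpi array the deposited values equalled log10 of that log2 ratio, to within the tolerance of 1e-04, at 144 of 144 spots. Some deposited ratios were positive because both background-subtracted signals were negative, at 13 to 27 spots per array. The authors' deposited table of the whole series held a linear ratio per oligo. Set against the spot ratios, its columns for 0 to 9 hpi were unscaled, and those for 12 to 72 hpi had been divided by the ratio of the control oligo CfVD1, which is 1 in each of them. The direction of that table is Cy3 over Cy5. Its column medians were 1.27, 2.00, 0.394, 0.170, 0.645, 1.16, 0.871, 1.04, 1.11, 1.10 and 1.07 in order of time. It covered 46 oligos at 0 hpi and 304 at 72 hpi. Neither the deposited log2 values nor the deposited ratios were used for the main results.

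The main values were computed from the deposited median intensity of each spot. Both channels were corrected with the normexp method of limma 3.58.1 (offset 50) in R 4.3.3, and log2 of Cy3 over Cy5 was averaged over the spots of an oligo. No loess, centring or scaling between arrays was applied, because viral RNA was expected to rise for nearly all probes and viral DNA is the reference. A probe was treated as above blank level if its mean background-subtracted Cy5 signal exceeded the 95th percentile of the blank spots on every array, which held for 135 sense and 137 complement probes. A Cy3 signal was called detected if the mean log2 raw signal of the probe exceeded the mean plus 3 SD of the 36 spots of HAT4, YaaJ and EcUDP. The files do not say what these 3 oligos are, and they were taken as the background level after the data were examined, because their Cy3 signal lay below the local background (median difference of -77 at 0 hpi). Detected, or detected over background, thus means brighter than these oligos and need not mean above the local background. The limit followed their scatter on each array. cforf077 was not detected at a raw Cy3 signal of 229 at 6 hpi but was at 178 at 9 hpi. A fold in the Cy3 channel written as at least a value sets the mean of the later window against, for each array of the earlier window, the higher of the lowest corrected signal of a detected ORF probe on that array and the probe's own signal. The bounds for the host oligos at 72 hpi and for cforf019 at 0 hpi follow the same rule. The size of a fold depends on the background correction, more so where the lower signal was near background.

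The time trend was fitted with limma's lmFit and eBayes as the log2 ratio against log2(hpi + 1) over the 11 arrays, leaving 9 residual degrees of freedom. A second limma fit over 10 arrays had 3 windows: 1, 3 and 6 hpi, then 9, 12 and 18 hpi, then 24, 36, 48 and 72 hpi. It compared each window with the one before. Tests were two-sided with Benjamini-Hochberg adjustment over the 146 sense probes and a threshold of 0.05. The 146 complement probes and the 18 controls were fitted and adjusted separately, each over its own set. Times inside a window are not replicates, so the spread of that fit holds the change within a window. Onset was the first time at which an ORF was at least 2-fold above the 0 hpi array and remained so at the next time, with no test. For 72 hpi, the last time, the first condition alone was asked. Relations with time over arrays were given as Pearson's r and Spearman's rho, each with a two-sided permutation test of 100000 resamples, for which the smallest p is 1e-05, and were adjusted over 4 relations. In simulated data of 146 ORFs with 40 changed, repeated 20 times, the trend fit recovered 84.4% of ORFs with a slope of 0.3 and 100% with a slope of 1. The fit of 24 to 72 against 9 to 18 hpi recovered 51% of changes of 1 and 100% of changes of 3, on the log2 scale. Between 3.06% and 4.72% of the simulated calls were false. The simulated noise was independent between ORFs, changes went in both directions, and the window changes were a step at 24 hpi. Shifts shared by the probes of an array and change within a window were not simulated, so these rates need not hold for the real arrays.

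Cy3 holds the RNA on every array and Cy5 the reference, with no dye swap, so a dye effect of a probe would stay in its ratio at every time. Early and late arrays correlated below 0 across all 310 oligos (r = -0.31 for 0 against 72 hpi, and -0.41 at the lowest, for 1 against 72 hpi). At 0 hpi the ratio correlated with the Cy5 signal at r = -0.85 over sense probes and -0.61 over complement probes. With Cy3 near background on most probes, the early ratio thus largely follows the inverse of Cy5. The direction of the ratio was kept as the labels give the dyes. No scan date or slide number was used here. The alternatives tried were other background corrections, centring on sense probes, complement probes or the oligos At1 and At2, Cy3 alone, a scaled Cy5 channel, the authors' table, a filter on dim probes, spot medians, other windows, thresholds and time scales, and leaving out each array. Figures were drawn with matplotlib 3.10.9.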

Results

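Transcripts of CfMNPV were followed from 0 to 72 h after infection of Cf203 insect cells, on arrays that held a probe for each of 146 viral ORFs and a probe for the complement of each. The 11 arrays were single samples, 1 for each time, and there were no replicate arrays. Spots of a probe on the same array agreed closely: the median SD over spots of the log2 ratio was 0.16 at 0 hpi and 0.08 at 72 hpi. The spot SDs given below measure only that error within an array. The raw Cy3 signal of the median sense probe went from 89 at 0 hpi to 3273 at 72 hpi, against 80 and 118 for the oligos HAT4, YaaJ and EcUDP taken as background. These oligos read 155 at 3 hpi and 143.5 at 6 hpi. The median local background was 162 at 0 hpi and 203 at 72 hpi, so the median sense probe lay below it at 0 hpi. The Cy5 signal of viral DNA on the median sense probe lay between 155 at 9 hpi and 474 at 1 hpi. 11 sense and 9 complement probes read no higher than the blank spots in Cy5 on at least 1 array.

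The first question was how the overall level of viral transcripts changed through infection. The median log2 ratio of cDNA to viral DNA over the 146 sense probes was -1.92 at 0 hpi and -2.46 at 1 hpi. It was 0.11 at 12 hpi, 1.20 at 24 hpi, 2.04 at 36 hpi, 2.82 at 48 hpi and 3.74 at 72 hpi. In the Cy3 channel, 26 of the 135 sense probes above blank level were detected at 0 hpi, 21 at 1 hpi and 3 at 3 hpi. The number was 44 at 6 hpi, 67 at 9 hpi, 61 at 12 hpi, 102 at 18 hpi, 132 at 24 hpi and 134 from 36 hpi on. Detected means brighter than HAT4, YaaJ and EcUDP, whose limit moved from array to array and could lie under the local background. The early counts are therefore no course of signal over the local background. A ratio difference from a time at which Cy3 was not detected, or lay under the local background, is not a measured fold. From 24 to 72 hpi, with most probes detected, the median rose by 2.54 on the log2 scale. The median log2 ratio increased with log2(hpi + 1) over the 11 arrays, with Pearson's r = 0.949 (permutation p = 3e-05, adjusted 0.00012) and Spearman's rho = 0.991 (permutation p = 1e-05, the smallest the resamples can give, adjusted 2e-05). Without the 0 and 1 hpi arrays, the 2 farthest from the median time on this scale, r was 0.970. In the authors' table, whose columns from 12 hpi on were divided by the ratio of the oligo CfVD1, r was 0.0736. The log2 ratio of CfVD1 itself rose from -0.19 at 12 hpi to 3.65 at 72 hpi. The division removes a rise shared with that oligo, so this r is no separate test of the shared rise.

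**Figure D1:**
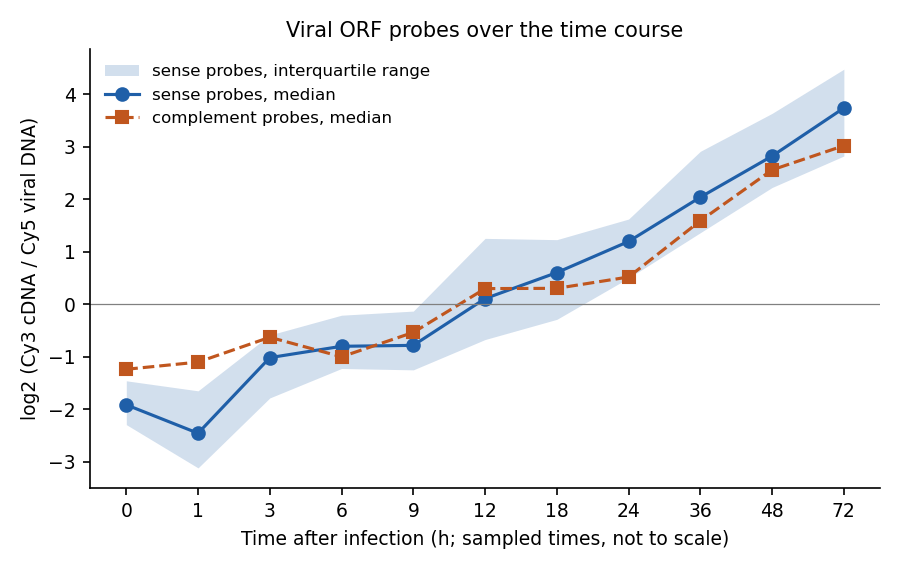
Median log2 ratio of Cy3-labelled cDNA to Cy5-labelled viral DNA (vertical axis) at each sampled time in hours after infection (horizontal axis, not to scale) for 146 sense probes (circles, with the range from the 25th to the 75th percentile over probes shaded) and 146 complement probes (squares). The sense median went from -1.92 at 0 hpi to 3.74 at 72 hpi and the complement median from -1.24 to 3.02.

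Nearly all sense probes rose with time. Of the 146 sense probes, 133 rose and 0 fell in the limma trend at an adjusted p of 0.05, and the counts at an unadjusted p of 0.05 were also 133 and 0. Among the 146 complement probes 134 rose too, as given below. Viral DNA in the Cy3-labelled sample stays open as a source of their late signal and could light sense probes as well. The rise of the sense probes is therefore not known to come from transcripts alone. The median slope was 0.97 log2 units for each doubling of hpi + 1. The steepest slopes were those of cforf077 (1.57 ± 0.15, SE, limma adjusted p = 1.77e-06) and cforf076 (1.48 ± 0.14, SE, limma adjusted p = 1.39e-06). cforf077 read a log2 ratio of -2.42 ± 0.21 (spot SD, 3 spots) at 0 hpi, 1.76 ± 0.12 at 12 hpi and 5.27 ± 0.06 at 72 hpi. Its Cy3 signal was not detected from 0 to 6 hpi, so its slope rests in part on values at background, and in Cy3 alone cforf076 was the steeper of the 2 (1.68 against 1.52). Of the 13 ORFs that did not pass, 11 were probes at blank level. Of the 135 sense ORFs above blank level, 113 had their highest ratio at 72 hpi, 21 at 48 hpi and 1 at 36 hpi. The ORFs with the highest ratio at 72 hpi were cforf131 (6.29 ± 0.02, spot SD, 3 spots) and cforf129 (6.25 ± 0.05, spot SD, 3 spots). Once each array was centred on the median of the sense probes, which removes the shared rise, 30 ORFs rose and 30 fell relative to that median. With the authors' table, where the division by CfVD1 removes a rise shared with it from 12 hpi on, 65 ORFs rose and 6 fell.

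The windows of 1 to 6 and 9 to 18 hpi addressed which ORFs rose before and during the middle of the time course. 10 ORFs were higher at 9 to 18 hpi than at 1 to 6 hpi and 0 were lower at an adjusted p of 0.05, with 35 higher and 0 lower at an unadjusted p of 0.05. The median change over the 146 ORFs was 1.28 on the log2 scale. It was 0.78 without the 1 hpi array and 1.65 without the 6 hpi array, the extremes when 1 array was left out. The largest differences in ratio were those of cforf023 (4.04 ± 0.81 log2, SE, limma adjusted p = 0.0284) and cforf127 (4.02 ± 0.83 log2, SE, limma adjusted p = 0.0284). The ratio of cforf023 was -0.01 at 6 hpi, 1.40 at 9 hpi and 3.13 at 12 hpi, and that of cforf127 was -0.99, 0.29 and 2.21. Both then changed little between 18 and 24 hpi, cforf023 from 3.46 to 3.54 and cforf127 from 3.17 to 3.47. In Cy3 each of the 2 was detected on 1 of the 3 arrays from 1 to 6 hpi, so their sizes rest on a baseline near background. The calls in this comparison were fragile. The count was 0 without the 1, 3, 12, 18, 36 or 48 hpi array, 25 without 9 hpi and 21 without 24 hpi, and it was 2 in the Cy3 channel alone, where cforf127 had an adjusted p of 0.0901 with limma. It was higher still in the authors' table and with 24 hpi in the middle window, as given below. Relative to the median sense probe of each array, 14 ORFs were higher and 5 lower.

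The median change in ratio was larger late than in the middle of the time course. The middle change starts from 1 to 6 hpi, when Cy3 was not detected on most sense probes, so it can be understated. At 24 to 72 hpi, 122 of the 146 sense ORFs were higher than at 9 to 18 hpi and 0 were lower at an adjusted p of 0.05, with 124 higher and 0 lower at an unadjusted p of 0.05. The median change was 2.37 on the log2 scale. The difference in ratio was largest for cforf135 (5.50 ± 0.95 log2, SE, limma adjusted p = 0.0106), but its Cy3 signal was not detected at 9, 12 or 18 hpi, so that its rise is known only as at least 67.5-fold in Cy3. Its ratio was -0.74 at 18 hpi, 1.69 at 24 hpi, 4.54 at 36 hpi and 6.16 at 72 hpi. cforf137 followed (4.53 ± 0.96 log2, SE, limma adjusted p = 0.0106), with ratios of -0.13 at 18 hpi, 1.23 at 24 hpi, 4.06 at 36 hpi and 6.04 at 72 hpi. Its Cy3 signal was detected on 1 of the 3 arrays from 9 to 18 hpi. 9 of the 10 ORFs higher at 9 to 18 than at 1 to 6 hpi were among the 122. Of the 24 ORFs that did not pass, 11 were at blank level. The number of calls rested on the 9 and 48 hpi arrays, with 34 ORFs higher without 9 hpi and 76 without 48 hpi, and it was 52 with 9 hpi moved to the first window, 36 with no background correction and 25 in the authors' table, where 2 fell. Relative to the median sense probe of each array, 10 ORFs rose and 17 fell, and relative to the median complement probe 27 rose and 12 fell.

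**Figure D2:**
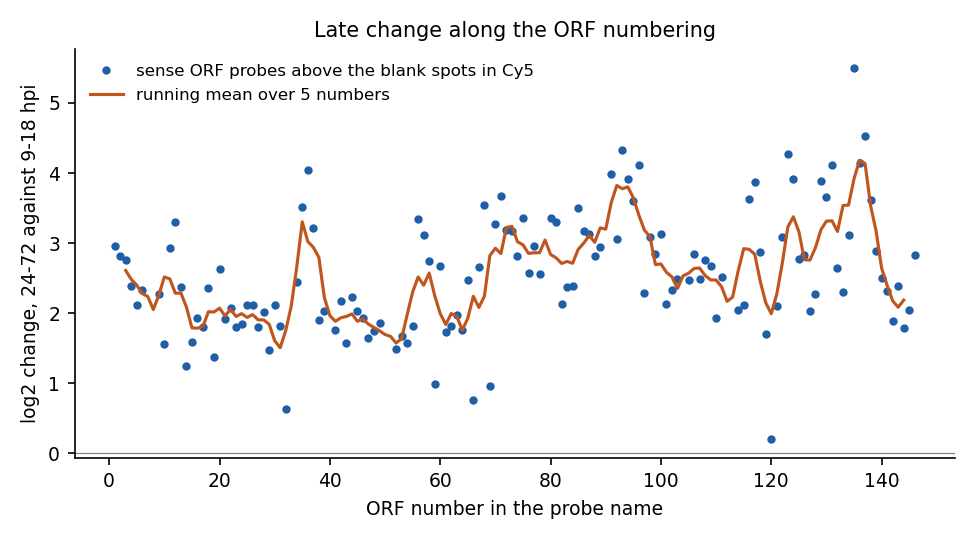
Change in log2 ratio from 9-18 hpi to 24-72 hpi (vertical axis) of the 135 sense ORF probes above blank level (points), by the number in the probe name (horizontal axis), with the running mean over 5 numbers (line). All points lie above 0, and the highest is that of cforf135 at 5.50.

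Onset was read from each ORF's own value at 0 hpi, without a test, since each time had 1 array. By the log2 ratio, 25 ORFs were 2-fold above 0 hpi from 3 hpi, 40 from 6 hpi, 13 from 9 hpi, 33 from 12 hpi, 13 from 18 hpi, 6 from 24 hpi, 1 from 36 hpi, 2 from 48 hpi and 1 from 72 hpi, while 12 had no onset. The median onset was 9 h. Cy3 was detected on 26 of the 135 sense probes above blank level at 0 hpi, 3 at 3 hpi and 44 at 6 hpi. Most ratio onsets at 3 hpi therefore rest on Cy3 signals not detected over HAT4, YaaJ and EcUDP and on the Cy5 signal. They are no measured 2-fold rises. By the Cy3 signal alone, 3 ORFs had their onset at 3 hpi, 5 at 6 hpi, 18 at 9 hpi, 74 at 12 hpi and 14 at 18 hpi, and the median was 12 h. The number with onset by 6 hpi was therefore 65 by the ratio and 8 by Cy3 alone, and 54 ORFs had the same onset in both. By Cy3 relative to the oligos At1 and At2, a setting chosen after the data were seen, it was 62. By the ratio it was 40 with the Cy5 channel scaled to the same median on each array, 107 with no background correction, 17 without the 6 hpi array and 1 with a 4-fold threshold. Of the ORFs with onset at 3 hpi, cforf019 had the largest ratio change, 3.42 log2 units over 0 hpi. It read a raw Cy3 signal of 97 ± 3.5 at 0 hpi, not detected over background, and 703 ± 35 at 3 hpi (spot SD, 3 spots), a rise of at least 7.85-fold after correction. At 6 hpi the raw signal had fallen to 311 ± 26 and its ratio from 1.74 to 0.19, and the corrected Cy3 signal was 0.98 log2 units over 0 hpi, under 2-fold, so that its onset by Cy3 alone was at 9 hpi. Next was cforf001, with a ratio 2.12 log2 units higher at 3 hpi. Its raw Cy3 signal was 317 ± 16 at 3 hpi, which was not detected, and 290 ± 19 at 24 hpi (spot SD, 3 spots), the first time it was detected. The detection limit was higher on the 3 hpi array, so its detection only at 24 hpi does not show that its signal was absent before.

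**Figure D3:**
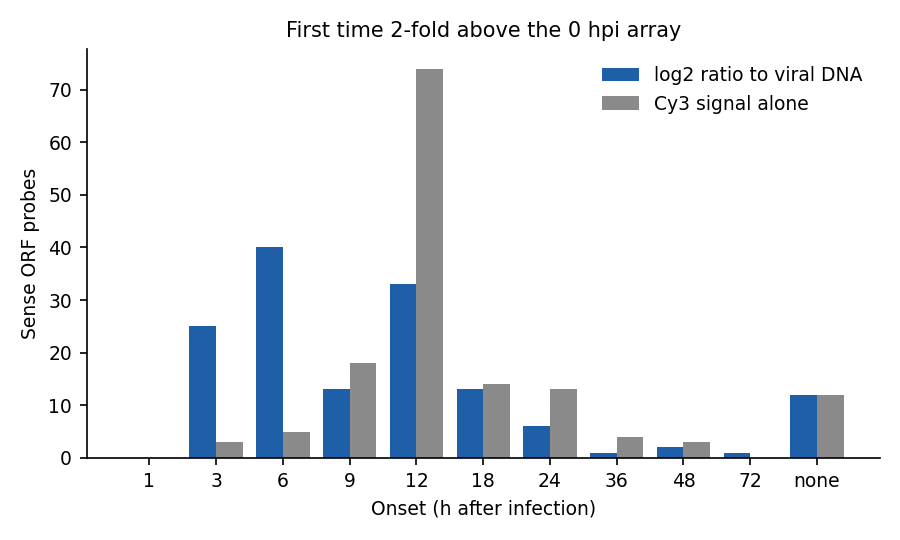
Number of sense ORF probes (vertical axis) by the first time in hours after infection at which they were at least 2-fold above the 0 hpi array and remained so at the next time, if there was one (horizontal axis, none for no such time). Dark bars use the log2 ratio to viral DNA and grey bars the Cy3 signal alone, which put 65 and 8 ORFs by 6 hpi.

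The complement probes addressed whether signal was confined to the sense probe of each ORF. Probes of both kinds rose: 134 of the 146 complement probes rose and 0 fell in the limma trend, with 134 and 0 at an unadjusted p of 0.05 and a median slope of 0.69. The number rising was 1 relative to the median sense probe of each array, 22 relative to the median complement probe and 39 in the authors' table. At 24 to 72 against 9 to 18 hpi, 98 complement probes were higher and 0 lower. At 9 to 18 against 1 to 6 hpi, limma called 0 in either direction, with 22 higher at an unadjusted p of 0.05. The steepest slopes were those of nc-cforf092 (1.36 ± 0.19, SE, limma adjusted p = 5.9e-05) and nc-cforf077 (1.14 ± 0.14, SE, limma adjusted p = 3.98e-05). Over ORFs, the median of the sense ratio minus the complement ratio was -0.59 at 0 hpi, -1.28 at 1 hpi and -0.58 at 3 hpi. From 24 hpi on it read 0.60, 0.58, 0.46 and 0.73, with no steady rise. At 0, 1 and 3 hpi Cy3 differed little between sense and complement (-0.04, 0.02 and -0.15). Median raw Cy5 was higher on sense probes (257 against 167 at 0 hpi), so the early negative values lay in Cy5. The difference in ratio increased with log2(hpi + 1) over the 11 arrays (r = 0.881, permutation p = 0.00036, adjusted 0.00048). Spearman's rho was 0.900 (permutation p = 0.00034, adjusted 0.000453), and r was 0.856 without the 0 and 1 hpi arrays. In Cy3 alone the difference was -0.04 at 0 hpi and 1.72 at 72 hpi (r = 0.803, permutation p = 0.00314, adjusted 0.00314). It did not grow steadily: it was 1.63 at 24 hpi, 0.99 at 36 hpi and 0.55 at 48 hpi, and the 72 hpi value rests on 1 array. Among the 127 pairs with both probes above blank level, the median difference in ratio at 72 hpi was 0.74. The sense and complement probes lay in different blocks of the spot list. The control CfVD1, present in all 4 blocks, differed between the sense and the complement blocks by at most 0.16 on the log2 scale on any array. The control CfVD2 differed by -0.39 at 0 hpi, -0.78 at 1 hpi and 0.21 at 72 hpi, in the direction of the sense minus complement difference, so part of that difference can come from position. With the CfVD2 difference subtracted on each array, a setting chosen after the data were seen, the median was -0.20 at 0 hpi and 0.52 at 72 hpi (r = 0.742, permutation p = 0.008). In the authors' table the relation was r = 0.157.

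Control oligos showed what the cellular RNA and the array background did meanwhile. The oligos named actin and tublin, for the cytoskeletal proteins, and GAP and EF1-a were detected in Cy3 on every array through 48 hpi. At 72 hpi actin, tublin and GAP were at their lowest and not detected over background, while EF1-a was detected and read 9.40, above its 8.69 at 9 hpi. Over the 10 arrays from 0 to 48 hpi the log2 Cy3 signal of actin was 11.36 ± 0.64 (SD, n = 10), and at 72 hpi it was 7.61, against 7.46 for the blank spots, so that it was at least 7.96-fold lower. The 72 hpi signal was at least 2.76-fold lower for tublin and at least 1.77-fold lower for GAP, and 1.75-fold lower for EF1-a. The files do not say what the oligos At1 and At2 are, and they are not known to be a stable reference. Their mean log2 Cy3 signal had an SD of 0.51 over the 10 arrays to 48 hpi and was lowest of these at 9 hpi. At 72 hpi the mean of At1 and At2 was 1.63-fold lower. Relative to that mean, actin was at least 4.88-fold lower, tublin at least 1.69-fold and GAP at least 1.09-fold, while EF1-a was 1.07-fold lower. In the limma trend over all times none of the 4 passed on the log2 ratio, with actin nearest (slope -0.41 ± 0.15, SE, adjusted p = 0.0526), while in Cy3 alone actin passed (limma adjusted p = 0.0492). The 72 hpi difference rests on 1 array. Of the 18 controls, 6 rose in the trend, namely CfVD1, CfVD2, CfVD3, CfVD4, Cfmix and Cfmix-nc. The raw Cy5 signal at 0 hpi was 1392 for CfVD1, 394.5 for CfVD2, 1005 for Cfmix and 1300.5 for Cfmix-nc, against 27 for the blank spots. These oligos thus took up the labelled viral DNA, and their rise is not that of non-viral controls. CfVD3 and CfVD4 read only 59.5 and 42 in Cy5. CfVD1 had a slope of 1.09 ± 0.13 (SE, limma adjusted p = 2.19e-05). The 3 spots of Cfmix in 1 of the 4 blocks read 1.70 at 72 hpi and those of Cfmix-nc 1.72, like the blank spots at 1.73, and without them the 2 oligos still rose (slopes of 1.36 and 1.34). The blank spots, HAT4, YaaJ and EcUDP did not pass. On the 9 hpi array the 4 host oligos were dim, with EF1-a, GAP and tublin at their lowest of the arrays to 48 hpi.

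**Figure D4:**
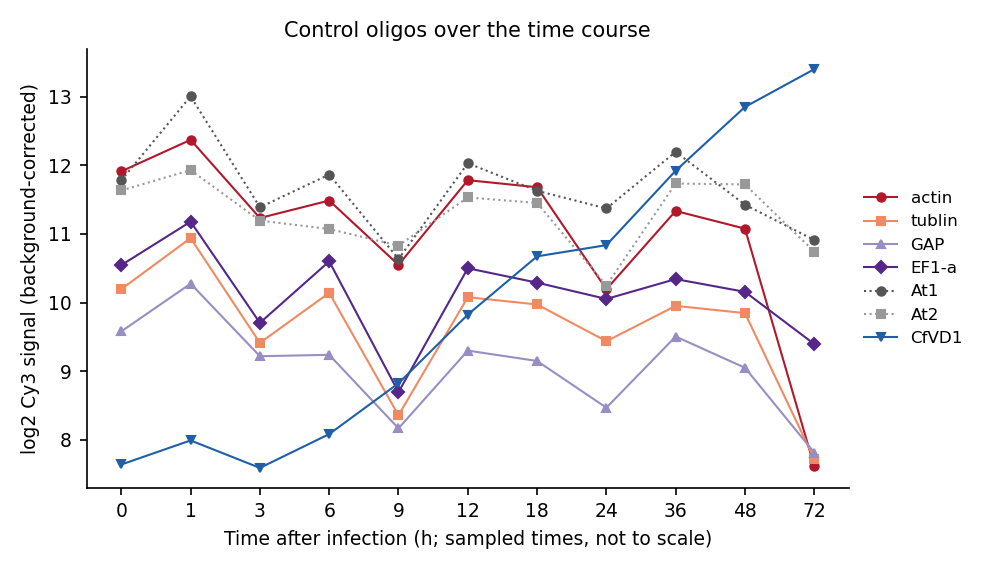
Background-corrected log2 Cy3 signal (vertical axis) of control oligos at each sampled time in hours after infection (horizontal axis, not to scale), as the mean over 12 spots. Actin went from 11.91 at 0 hpi to 7.61 at 72 hpi and CfVD1 from 7.64 to 13.40.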

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

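The tests in this part were chosen after the 0 hpi signals had been seen. The 0 hpi array holds signal on viral probes that no comparison above uses on its own. On it, 2 probes exceeded 10 times the level of the background oligos: cforf066 had a raw Cy3 signal of 3758 and its complement probe nc-cforf066 one of 6020, against 81 for HAT4, YaaJ and EcUDP. The next brightest ORF or complement probe read 627, and the median of the other 270 probes above blank level was 90.9.

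Viral DNA of the whole genome in the 0 hpi sample as the whole cause is argued against, since 1.11% of the other probes, 3 of 270, reached 10% of the Cy3 signal of cforf066, while 98.5% reached 10% of its Cy5 signal from viral DNA. Viral RNA of this ORF alone at 0 hpi was not tested and stays open. In Cy3, 80 of the 270 other probes were brighter than HAT4, YaaJ and EcUDP. That limit lay under the local background of 162, and cforf024 passed it at 110. Detection on these 80 thus does not by itself show viral signal. A smear between spots is argued against as well: the probes listed beside the pair reached at most 8.69% of the signal of cforf066, and the pair lies in different blocks of the spot list. Binding of cellular RNA by both probes may be a candidate explanation and stays open. Relative to the mean of the 4 host oligos, the log2 Cy3 signal of each of the pair differed from its 0 hpi value by at most 1.28 from 1 to 9 hpi, and by at most 1.59 between any 2 arrays from 0 to 9 hpi, while viral RNA of the same ORF cannot be separated from it at later times. The signal of cforf066 was 11.87 at 0 hpi, 12.17 at 1 hpi, 11.44 at 3 hpi, 10.96 at 6 hpi, 11.12 at 9 hpi and 12.89 at 72 hpi on the log2 scale. That of nc-cforf066 was 12.55 at 0 hpi, 10.75 at 9 hpi and 12.50 at 72 hpi. No biological explanation was tested, and no probe sequence was used here.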

How the results depend on the processing

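Leaving out the 1 and 9 hpi arrays together, subtracting the block difference of CfVD1 or CfVD2, centring the Cy3 signal on At1 and At2, and reading onset from the first detection over background were chosen after the data were seen. Of 140 values of the comparisons under settings other than leaving out 1 array, 98 stayed on their side of the threshold or within 1.5 times the main count, 40 moved further and 2 lost their call. Only the correlations with time could be called reversed, because a count could only stay or move, and none of them was. Of 177 values for named ORFs and medians under those settings, 2 reversed. The count of rising ORFs in the trend lay between 131 and 134 when each array was left out in turn, and 0 fell. The overall level kept an r of 0.938 to 0.976 and the sense minus complement difference one of 0.863 to 0.915. For 9 to 18 against 1 to 6 hpi that range was 0 to 25 ORFs higher, for 24 to 72 against 9 to 18 hpi 34 (without 9 hpi) to 129, both with 0 lower, and for onset by 6 hpi 17 to 78. The controls rising were 5 to 6 and those falling 0 to 2. The 0 hpi array is the baseline of the onsets, which had no value without it.

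With no background correction 0 ORFs were higher at 9 to 18 than at 1 to 6 hpi and 36 at 24 to 72 than at 9 to 18 hpi, 107 had their onset by 6 hpi and 2 controls fell. Plain subtraction kept the counts near (135, 13 and 93) and made 1 control fall, and spot medians 2. It made the sizes larger: the median slope was 2.24, the median changes 3.83 and 4.83 log2, and the changes 8.58 for cforf023, 6.24 for cforf127 (limma adjusted p = 0.059, the call lost), 10.01 for cforf135 and 8.09 for cforf137. The sense minus complement difference kept an r of 0.845 with the block difference of CfVD1 subtracted and 0.742 with that of CfVD2. Centred on the median sense probe, 30 ORFs rose and 30 fell in the trend, 14 rose and 5 fell from 1-6 to 9-18 hpi, 10 rose and 17 fell from 9-18 to 24-72 hpi, and 2 had their onset by 6 hpi. The median changes were then -0.12 and -0.10, because the centring removes the shared rise. Centred on the median complement probe, 89 rose and 16 fell in the trend, 16 rose from 1-6 to 9-18 hpi, 27 rose and 12 fell from 9-18 to 24-72 hpi, and 18 had their onset by 6 hpi. Centred on At1 and At2, 18 were higher at 9 to 18 hpi and 102 had their onset by 6 hpi. With Cy3 alone these were 2 and 8, with 1 control falling, and with a scaled Cy5 channel 3 and 40, with 1 control falling. 132 of the 133 rising ORFs and 121 of the 122 late ones were called in Cy3 alone as well.

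With the authors' table, the trend gave 65 ORFs rising and 6 falling, while 49 rose and 1 fell from 1-6 to 9-18 hpi, 25 rose and 2 fell from 9-18 to 24-72 hpi, 4 had their onset by 6 hpi and 6 controls fell. The r of the overall level was 0.0736 and that of the sense minus complement difference 0.157. That table divides the columns from 12 hpi by the CfVD1 ratio, which itself rose, so a rise shared with it is removed. It also lists few ORFs early, 16 at 0 hpi. Without dim probes 18 ORFs were higher at 9 to 18 than at 1 to 6 hpi. With 9 hpi in the first window the counts were 23 and 52, and with 24 hpi in the middle window 55 ORFs were higher in the middle. A 4-fold threshold left 1 ORF with onset by 6 hpi. Cy3 centred on At1 and At2 gave 19 ORFs higher at 9 to 18 hpi, and without both the 1 and 9 hpi arrays 43 were higher at 24 to 72 hpi. The cause of the other differences was not tested.

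Signal over background limits the early times: at 3 hpi 3 of the 135 sense probes above blank level were detected in Cy3. The differences of the host oligos at 72 hpi also depend on the background, and those of actin, tublin and GAP are no measured folds because their 72 hpi signal was not detected: with normexp, none and plain subtraction they read 13.4-fold, 11.8-fold and 326-fold for actin, 4.32-fold, 3.98-fold and 32.9-fold for tublin, 2.60-fold, 2.63-fold and 8.32-fold for GAP, and 1.75-fold, 1.76-fold and 2.18-fold for EF1-a. Tests of the temporal gene lists were not run, because the files give no gene names. No paired analysis was possible because each time had 1 array.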

Other observations

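The tests of the complement probes, of the order of spots and of the Cy5 signal, and the counts of other splits, were written before their results were seen, except that viral DNA was tested again, against Cy5, and the gradient across the slide was tested, under rules set after those values were seen. That ORFs with adjacent numbers had similar changes had been seen before it was tested.

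The late time courses differed between ORFs in shape. The ratio of cforf127, among the largest middle rises, was -2.44 at 0 hpi, 3.17 at 18 hpi and 4.52 at 72 hpi, so that most of its rise lay before 18 hpi. That of cforf135, the largest late rise, was -2.01 at 0 hpi, -0.74 at 18 hpi and 6.16 at 72 hpi. These 2 were compared after their values had been seen, and no ORFs were grouped by shape. Among the complement probes, nc-cforf092 reached a ratio of 6.80 ± 0.12 (spot SD, 3 spots) at 72 hpi, with a raw Cy3 signal of 94.7 at 0 hpi and 47618 at 72 hpi. At 72 hpi, 94.2% of the 137 complement probes above blank level were detected over background in Cy3.

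Late signal on the complement probes could come from viral DNA in the Cy3-labelled sample, from RNA of neighbouring ORFs that runs across the probe, or from the RNA of the same ORF. All 3 stay open. For viral DNA as the whole cause, the SD over 99 probes of the change from 24 to 72 hpi was 11.8 times its spot error, but that error leaves out differences in response between probes, so the test does not bear on it. The Cy3 changes of these probes had 2.73 times the SD of their Cy5 changes, while Cy3 followed Cy5 across probes more closely at 72 hpi (r = 0.70) than at 24 hpi (r = 0.21). From 24 to 72 hpi the median ratios of sense and complement probes rose alike, by 2.54 and 2.50. From 12 to 72 hpi they rose by 3.63 and 2.72. The late change of a complement probe went with that of the 2 neighbouring sense probes, with its own sense probe held (partial Spearman correlation of 0.46 across 127 ORFs, against 0.18 at the 95th percentile of 137 shifted numberings). It also went with that of its own sense probe, with the neighbours held (0.57, against 0.16). ORFs are not independent replicates, and strand-specific labelling was not tested.

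ORFs with adjacent numbers had similar late changes: the Spearman correlation between neighbours was 0.54 across 126 pairs of sense probes (permutation p = 1e-04, the smallest that 10000 shuffles can give). Between adjacent complement probes it was 0.72, so the pattern was not confined to the sense probes. The files do not say whether the numbers follow the genome. A position effect repeated in each block of the spot list is argued against, because ORFs at the same place in the first and the second of the 4 blocks of the spot list correlated at 0.04 across 63 pairs. The brightness of probes in the viral DNA channel is also argued against for the sense probes. Their correlation was 0.45 once mean Cy5 was regressed out, against 0.18 at the 95th percentile of shuffled orders. A gradient across the slide stays open, as adjacent numbers are adjacent spots and no coordinates were used here. The correlation of the sense probes fell to 0.40 once the change in local Cy3 background was regressed out, which measures such a gradient only in part. Late RNA of neighbouring ORFs that is made together or overlaps may also account for it, and no separate data tested that here.

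The counts of ORFs past the threshold were set against other arrangements of the arrays. For the trend, 1 of 100 assignments of the times to the arrays, the real one, gave as many as 133 rising or falling ORFs, a share under 0.05. The highest other gave 131, so the count hardly separates the real order. Probes shifted together by array, so the count adds little to the relation of the array medians with time. Reassigned times cannot address a drift that follows time in single arrays. For 9 to 18 against 1 to 6 hpi the 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 10 ORFs and the highest other 0. For 24 to 72 against 9 to 18 hpi, 2 of the 35 splits of 7 arrays gave at least the real 122, so chance cannot be excluded at 0.05. The other, with 126, is the split that moves 24 hpi to the earlier window and keeps the order of times.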
